A study of Homo sapiens with 15 samples.

How the data were processed

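ChIP-seq was made from HEK293 cells that carried a retrovirus encoding wild-type or WBM-MYC with a FLAG tag, or the empty vector (anti-FLAG precipitates), and from untransduced HEK293 cells (WDR5 and IgG precipitates), with 3 libraries in each of the 5 groups, per the labels. The authors deposited peak lists, 1 for WT-MYC, 1 for WBM-MYC and 1 for WDR5. Each list has 3 columns, for chromosome, start and end, with no header, name, score or p-value. Per the submitters' processing notes, the build was hg19 and the tools included Bowtie 0.12.7, a read aligner, and CASAVA 1.8.2, Illumina's base calling software. The peak caller, its thresholds, the use of the vector and IgG libraries, and whether the replicates were pooled or their calls combined are not given in the sources used here. A peak list shows which sites passed an unstated threshold, so a site missing from 1 list may have been bound below it. Read depth is unknown, and a difference in depth between groups would change the number of peaks.

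Chromosome 9 holds peaks up to 140635243, which is 2303434 bp beyond the last gene of the GRCh38 gene table at hand. That table was therefore not used, and no peak was assigned to a gene. The planned share of peaks at promoters, the tests of fixed gene lists, the search for E-boxes (the sequence motif of MYC) and the random draws of promoters need an hg19 annotation or sequence and were not run.

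Groups were taken from the labels. Peaks counted as shared when they had at least 1 bp in common, and each share has an exact (Clopper-Pearson) 95% interval, which covers counting error over peaks only. Overlap beyond chance was tested by placing the peaks of 1 list at random on their own chromosome 1000 times, with widths kept, and by displacing each peak by 10 to 100 kb 1000 times, an addition made after the data were seen because sites cluster. Classes of peaks were compared with Fisher's exact test, two-sided, differences of shares have Newcombe intervals, and strata were combined with the Mantel-Haenszel odds ratio and an exact conditional test. Medians within a list were compared by permutation tests with 100000 resamples, two-sided. Distances between centres were taken over overlapping pairs and compared with 1000 random placements of 1 centre within the other peak. Overlapping neighbours within a list and sites along a chromosome are not independent, so peak-based p-values can be too small.

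The design called for the authors' score, or else the width, to rank peaks. Width hardly varies in the MYC lists, so position in the file was used in its place, an addition made after the data were seen. The lists are not sorted by chromosome position. Deciles and quartiles are the 10 and 4 equal parts of a list in file order, except for the 4 width quartiles of WDR5.

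Peaks named by position follow the rule fixed before the data were examined for the case that genes cannot be assigned, the first 5 of each part. Other regions were named after their values were seen. The end of chromosome 9 was defined as the gaps between WDR5 peaks that held at least 10 WT-MYC peaks, from the start of the earliest such gap to the last peak. Chromosomes and 5-Mb bins with at least 20 peaks in all lists together were compared between lists with Fisher's exact test and Benjamini-Hochberg adjustment. Long stretches were runs of at least 40 consecutive WDR5 peaks without a WT-MYC peak. For these stretches 2 further explanations were tested and then not weighed, since only 3 patterns are weighed. Lower DNA copy number came out against its prediction: a lower share of late WDR5 peaks inside was predicted, and a higher one was found. Choosing runs without WT-MYC by itself favours late WDR5 peaks, although the share was higher also among WDR5 peaks without WT-MYC (64.2 against 53.2%). Fewer DNA copies could also weaken WDR5 peaks and move them later, if file order follows peak strength. That test therefore decides nothing. A property of the region shared by both MYC pools came out as its prediction had it, with fewer WBM-MYC peaks inside, also when stratified by decile. Choosing runs of many WDR5 peaks raises the WDR5 share inside, which favours this outcome, and the stratified value rests on 2 peaks. Lower DNA copy number would itself be such a property, so this test does not decide either. The values are given among the other observations. For WDR5 overlap of WT-MYC peaks in fixed 5-Mb bins, 75 bins with at least 10 WT-MYC peaks were tested.

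The overlap code, placements, permutations and stratified odds ratio were tested on simulated data. Planted overlaps of 30% and 80% came back as 30.3% and 79.7%, a true odds ratio of 3 came back as 3.03, and 4% of random lists passed the placement test and 7% of null permutations passed at 0.05. Counts of overlapping WT-MYC and WDR5 peaks were the same with bedtools 2.31.1. Alternatives covered the overlap rule, merging of near peaks, autosomes alone, the leading 50% of each list, removal of the end of chromosome 9 and stratification. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.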

Results

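Chromatin immunoprecipitation followed by sequencing (ChIP-seq) mapped the binding of MYC and WDR5 in HEK293 cells, a human embryonic kidney line. MYC is a transcription factor that drives growth and proliferation genes. WDR5 is a scaffold protein of histone methyltransferase complexes at active promoters. Cells carried a retrovirus for FLAG-tagged wild-type MYC (WT-MYC), for a FLAG-tagged MYC deficient in binding WDR5 (WBM-MYC), or an empty vector, and the tag was precipitated with an anti-FLAG antibody. In HEK293 cells without a retrovirus, endogenous WDR5 was precipitated, with rabbit IgG as the control. The 15 libraries form 5 groups of 3 independent biological replicates. One peak list per group was analysed for WT-MYC, WBM-MYC and WDR5, so no spread between replicates can be given and every interval and test below treats peaks as the units. Peaks of the vector and IgG libraries, and read depth, were not analysed here. All coordinates are hg19.

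WT-MYC had 2527 peaks, WBM-MYC 690 and WDR5 17171. Together they covered 1.21, 0.311 and 7.45 Mb of the genome, respectively. Nearly all MYC peaks had a fixed width: 97.9% of WT-MYC peaks spanned 496 bp and 99.3% of WBM-MYC peaks spanned 456 bp. WDR5 peaks ranged from 156 to 1704 bp, with a median of 419 bp. Each list reached 23 chromosomes, the autosomes and X. Some neighbouring peaks overlapped each other, and merging them left 2424 WT-MYC, 678 WBM-MYC and 15058 WDR5 regions.

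The first comparison asked how binding sites of wild-type MYC and of the WDR5-binding mutant relate. Most WBM-MYC peaks lay on WT-MYC peaks, while most WT-MYC peaks had no WBM-MYC counterpart. The shorter WBM-MYC list sets much of this asymmetry. Most WT-MYC peaks would lack a counterpart even if each WBM-MYC peak lay on a WT-MYC peak. Of the 690 WBM-MYC peaks, 497 shared at least 1 bp with a WT-MYC peak (72.0%, exact 95% interval 68.5 to 75.4%). Of the 2527 WT-MYC peaks, 527 shared at least 1 bp with a WBM-MYC peak (20.9%, 19.3 to 22.5%), which left 2000 WT-MYC peaks without one. Where peaks of both lists overlapped, their centres lay a median of 33 bp apart (interquartile range 10.5 to 72.5 bp). Randomly placed WBM-MYC peaks hit a mean of 0.795 WT-MYC peaks, and displacement of each peak by 10 to 100 kb gave a mean of 3.34 (permutation p = 0.001 for both, the smallest that 1000 random sets can give).

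By position along chromosome 1, the first shared WT-MYC peaks spanned 936052 to 936547, 936251 to 936746, 6259335 to 6259830, 6305061 to 6305556 and 8937945 to 8938440. The leading pair overlap each other, and the first 3 of these peaks also overlapped a WDR5 peak. The first WT-MYC peaks without a WBM-MYC peak spanned 1447088 to 1447583, 2344026 to 2344521, 6474302 to 6474797, 6640073 to 6640568 and 7676389 to 7676884. WDR5 peaks lay on those starting at 1447088, 2344026 and 6640073. The first WBM-MYC peaks without a WT-MYC peak started at 6614328, 16693671, 29507933, 43124181 and 53192078, and all 5 overlapped a WDR5 peak.

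Shared sites were concentrated at the beginning of the WT-MYC list. Among the first 253 peaks in file order, 153 overlapped a WBM-MYC peak (60.5%, 54.2 to 66.5%), and among the last 252 peaks 12 did (4.76%, 2.48 to 8.17%). The median line of WT-MYC peaks with a WBM-MYC peak was 532, against 1433.5 for those without (permutation test, two-sided, p = 1e-05, the smallest that 100000 permutations can give). The WBM-MYC list ran the same way, from 92.8% with a WT-MYC peak in its first decile (83.9 to 97.6%) to 50.7% in its last (38.4 to 63.0%). The lists carry no score and no source used here says how they are ordered, and file order was taken up after the data were seen. Peak width, the planned stand-in for a score, had a median of 496 bp with and without a WBM-MYC peak, so the planned test of medians was void. The few peaks under 496 bp are compared among the other observations.

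The next comparison set MYC binding beside WDR5 binding. Both forms of MYC lay mostly on WDR5 peaks. Of the 2527 WT-MYC peaks, 2096 overlapped a WDR5 peak (82.9%, 81.4 to 84.4%), and of the 690 WBM-MYC peaks 521 did (75.5%, 72.1 to 78.7%). Random placement gave means of 16.1 and 4.20 overlapping peaks, and displacement by 10 to 100 kb gave 36.2 and 9.83 (permutation p = 0.001 each, the smallest possible). WT-MYC overlap was thus 57.9-fold and WBM-MYC overlap 53.0-fold above the local mean. Neither random set was matched for promoters, since the planned promoter draws were not run. The folds therefore cannot show overlap beyond a shared preference for promoters. Along the WT-MYC list the share with WDR5 stayed between 79.0 and 88.5% from decile to decile. In the WBM-MYC list it was 53.6% in the first decile (41.2 to 65.7%) and between 72.5 and 84.1% in the others.

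**Figure D1:**
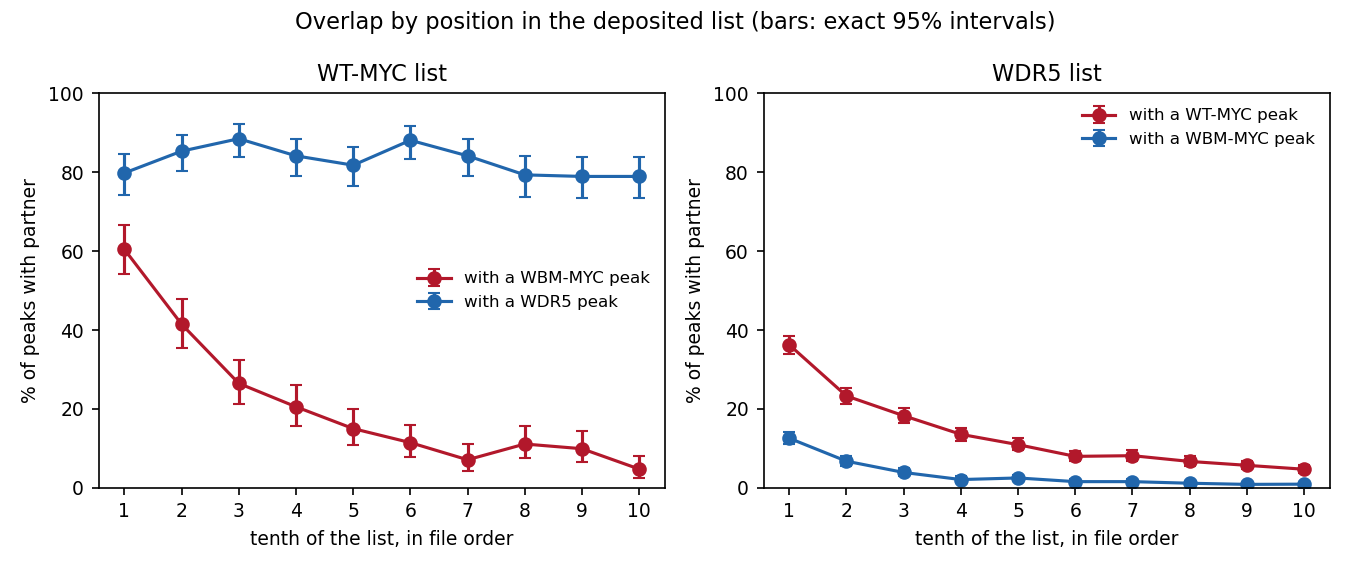
Share of peaks (%) that overlap a peak of another list, by decile of the WT-MYC list (left) and of the WDR5 list (right) in file order; points are shares and bars exact 95% intervals. The share of WT-MYC peaks with a WBM-MYC peak falls from 60.5 to 4.76%, while the share with a WDR5 peak lies between 79.0 and 88.5%.

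Overlapping WT-MYC and WDR5 peaks were centred close together. The median distance between their centres was 71 bp (interquartile range 28 to 138 bp, 2096 peaks), against a mean of 118.9 bp when WT-MYC centres were placed at random within the same WDR5 peaks. WBM-MYC and WDR5 centres lay a median of 80 bp apart (34.5 to 150.5 bp, 521 peaks), against 128.8 bp at random (permutation p = 0.001 each, the smallest possible). Distances to WDR5 were 78.5 bp for WT-MYC peaks shared with WBM-MYC and 69 bp for those not shared, a difference that did not pass the test (9.5 bp, two-sided permutation test, p = 0.140).

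**Figure D2:**
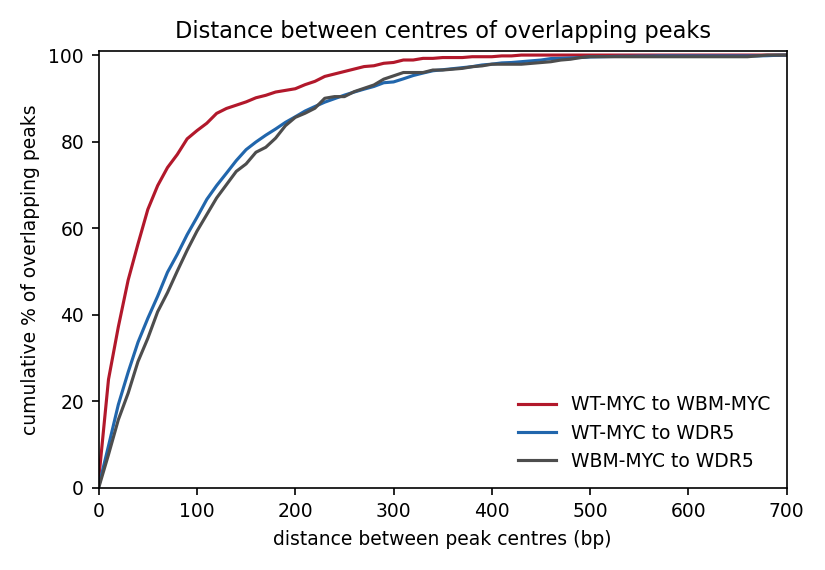
Cumulative share of overlapping peaks (%) against the distance between the centres of both peaks (bp), 1 line per pair of lists. The medians are 33 bp for WT-MYC to WBM-MYC, 71 bp for WT-MYC to WDR5 and 80 bp for WBM-MYC to WDR5.

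Seen from WDR5, few peaks overlapped a called peak of tagged MYC, and these came early in the WDR5 list. Low shares follow in large part from list length, with 2527 WT-MYC and 690 WBM-MYC peaks. Of the 17171 WDR5 peaks, 2329 overlapped a WT-MYC peak (13.6%, 13.1 to 14.1%) and 583 a WBM-MYC peak (3.40%, 3.13 to 3.68%). In the first decile 36.3% had a WT-MYC peak and 12.6% a WBM-MYC peak, against 4.72% and 0.932% in the last. WDR5 peaks with WT-MYC were wider, with a median of 476 bp against 409 bp (permutation test, two-sided, p = 1e-05, the smallest possible). By width quartile the share with WT-MYC was 6.52, 12.5, 20.2 and 15.05%, so it did not rise throughout. The widest quartile began at 624 bp, the commonest width, shared by 3482 WDR5 peaks (20.3%). That was also the median width in deciles 9 and 10 of the list, so width and file position are mixed here. WDR5 peaks that carried WBM-MYC mostly also carried WT-MYC, 438 of 583 (75.1%), against 1891 of the 16588 others (11.4%; Fisher's exact test, two-sided, odds ratio 23.5, 95% interval 19.3 to 28.7, p = 2.37e-264). That largely restates the 72.0% of all WBM-MYC peaks that lay on WT-MYC peaks, and is no separate evidence of joint binding at WDR5 sites. The first WDR5 peaks by position on chromosome 1, at 713879 to 714106, 839997 to 840380, 846265 to 846888, 851803 to 852426 and 860792 to 861208, overlapped neither MYC list.

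The last comparison asked whether WT-MYC sites shared with the mutant differed in WDR5 occupancy from those without it. Both classes lay mostly on WDR5 peaks. Among shared WT-MYC peaks 419 of 527 overlapped a WDR5 peak (79.5%, 75.8 to 82.9%), and among WT-MYC peaks without a WBM-MYC peak 1677 of 2000 did (83.9%, 82.2 to 85.4%). The odds ratio for shared peaks was 0.747 (0.583 to 0.962; Fisher's exact test, two-sided, p = 0.0225). A region at the end of chromosome 9, from 135906641 to 140635243, holds 46 WT-MYC and 30 WBM-MYC peaks and 3 WDR5 peaks, and without it the shares were 82.2 and 85.0% and the odds ratio no longer passed the test (0.814, 0.625 to 1.07, Fisher's exact p = 0.132). The call was also lost when an overlap had to cover 50% of the shorter peak (0.805, Fisher's exact p = 0.0638) or when only the first 50% of each list was used (0.838, p = 0.275).

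Stratified by quartile of file order, the odds ratio was 0.669 (0.513 to 0.871, Mantel-Haenszel estimate, exact conditional test, two-sided, p = 0.00356), and 0.715 (0.539 to 0.948, p = 0.0238) when the end of chromosome 9 was also left out. Without that region it was below 1 in the first 3 quartiles, at 0.717, 0.505 and 0.565, and 2.17 in the last, with only the second past its own Fisher's exact test (p = 0.0123). This stratification was chosen after the data were seen, in place of the planned one by score.

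WBM-MYC peaks without a WT-MYC peak overlapped WDR5 less often than the other MYC classes. Of these 193 peaks 126 had a WDR5 peak (65.3%, 58.1 to 72.0%), against 395 of the 497 WBM-MYC peaks shared with WT-MYC (79.5%, 75.7 to 82.9%). The difference was 14.2 percentage points (6.80 to 21.9; Fisher's exact test, two-sided, p = 0.000165), and 11.7 points (4.52 to 19.5, p = 0.00175) without the end of chromosome 9. This comparison was added after the data were seen.

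**Figure D3:**
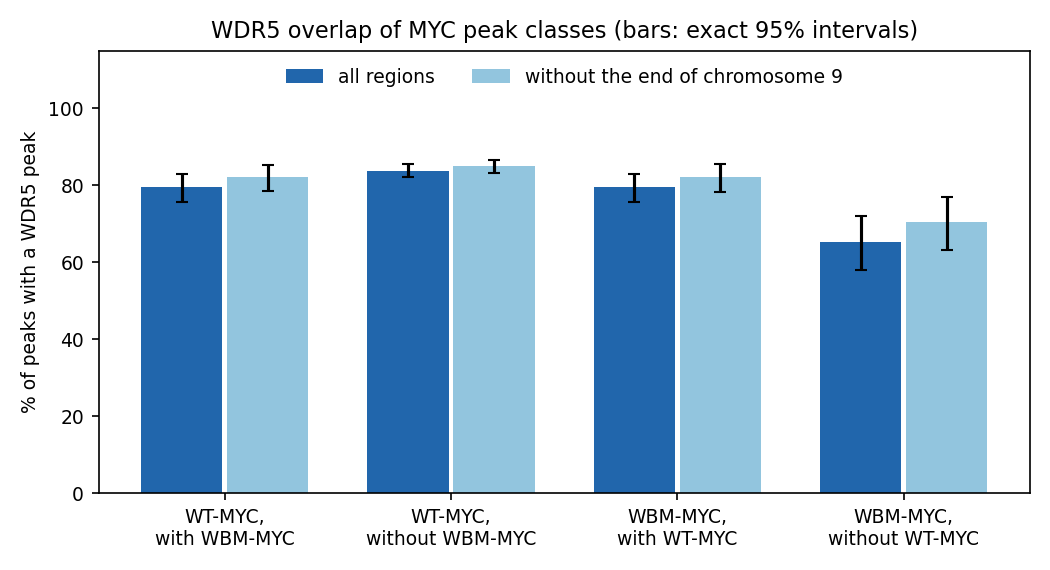
Share of peaks with a WDR5 peak (%) in 4 classes of MYC peaks, over all regions (dark) and without the end of chromosome 9 (light); error bars are exact 95% intervals. WBM-MYC peaks without a WT-MYC peak have the lowest share of the 4 classes, 65.3% and 70.4%.

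Along the genome, MYC peaks were not spread as WDR5 peaks were. Of 23 chromosomes, 5 held a larger share of WT-MYC than of WDR5 peaks (chromosomes 1, 6, 9, 10 and 17). A smaller share was held by 8, chromosomes 2, 3, 4, 7, 11, 14, 18 and X (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted over chromosomes). For WBM-MYC the counts were also 5 and 8. Chromosomes 5 and 21 took the place of 10 and 17 among the larger shares, and chromosome 22 that of X among the smaller. Chromosome 1 held 360 WT-MYC peaks, 14.2% of the list against 10.9% of WDR5 peaks (Fisher's exact test, adjusted p = 1.72e-05), and chromosome 11 held 77, 3.05% against 5.23% (adjusted p = 1.49e-05). Chromosome 18 held 16 WT-MYC peaks, 0.633% against 1.57% (Fisher's exact test, adjusted p = 0.000442). On chromosome 9 the excess came with the end region: outside it the shares were 2.94% of WT-MYC and 3.30% of WDR5 peaks (Fisher's exact test, unadjusted p = 0.365).

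**Figure D4:**
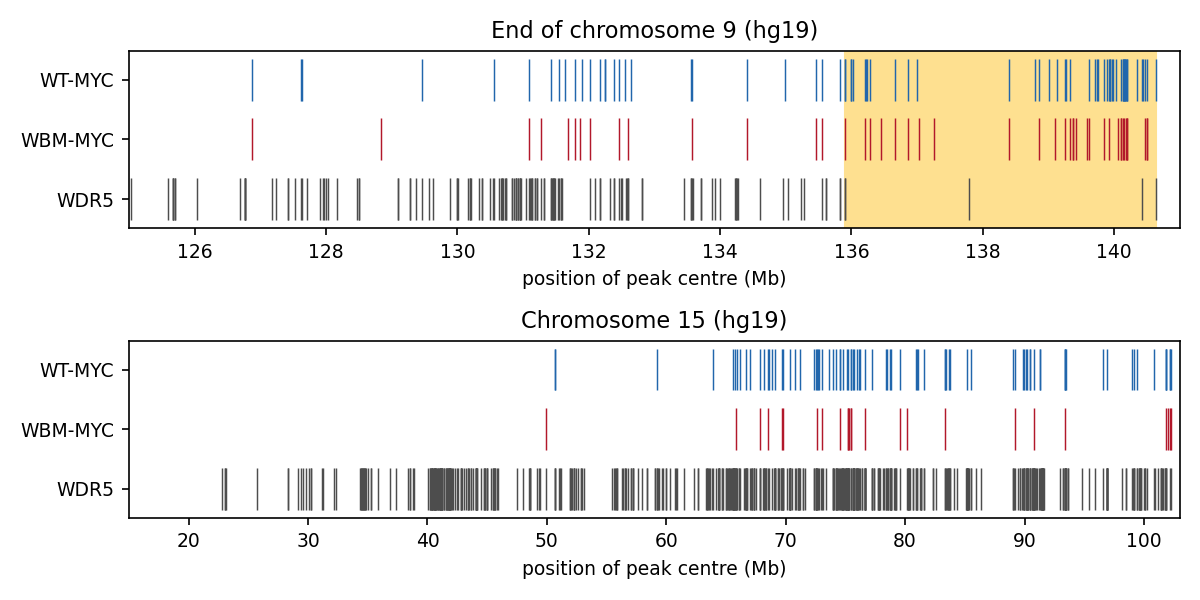
Positions of peak centres (Mb, hg19) on the last part of chromosome 9 (top, the end region shaded) and on chromosome 15 (bottom), 1 tick per peak and 1 line of ticks per list. The shaded region has 46 WT-MYC and 30 WBM-MYC peaks and 3 WDR5 peaks, and chromosome 15 has 142 WDR5 peaks before its first WDR5 peak with WT-MYC.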

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

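The tests of file position, of the end of chromosome 9 and of narrow peaks in this part were chosen after the results were seen. The test of WDR5 overlap by quartile was set out before its own value was known, and the one by decile was added later. The strata of both and the region they leave out were chosen after the data were seen.

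WDR5 overlap differed between the peaks found with only 1 form of MYC. It was 83.9% for WT-MYC peaks without a WBM-MYC peak and 65.3% for WBM-MYC peaks without a WT-MYC peak, a difference of 18.6 percentage points (11.99 to 25.7; Fisher's exact test, two-sided, p = 2.74e-09). Without the end of chromosome 9 the difference was 14.6 points (8.17 to 21.8, Fisher's exact p = 2.35e-06).

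The most prominent pattern is the 2000 WT-MYC peaks without a WBM-MYC peak. In large part this number restates that the WBM-MYC list is shorter, with 690 peaks. A technical explanation is that many lie near a calling threshold, which may be passed less often in the WBM-MYC libraries. The share with a WBM-MYC peak was 38.3 percentage points higher in the first quartile of the WT-MYC list than in the last (45.9 against 7.59%, interval 33.8 to 42.6). This is the direction needed if file order follows peak strength, which no source states. Weaker binding of WBM-MYC at all sites alike would give the same fall, so it cannot tell a technical from a biological cause. A biological explanation is loss at sites that WDR5 occupies. At equal file position and without the end of chromosome 9, shared peaks had WDR5 less often (odds ratio 0.715, 0.539 to 0.948), the direction this needs. By decile the odds ratio was 0.735 (0.551 to 0.981). The last quartile went the other way, and without strata the odds ratio was 0.814 (0.625 to 1.07). Material common to both anti-FLAG pools and lacking WDR5 would give an odds ratio below 1 too, so its direction does not decide. In the first decile of the WBM-MYC list, 92.8% had a WT-MYC peak and 53.6% a WDR5 peak, and vector peaks were not analysed. Of the 2000 peaks, however, 323 had no WDR5 peak. WBM-MYC was found at 419 of 2096 WT-MYC peaks with WDR5 (19.99%, 18.3 to 21.8%). It was found at 108 of 431 without WDR5 (25.06%, 21.03 to 29.43%), so most of these lacked WBM-MYC too. At the end of chromosome 9, where WDR5 peaks may be missing from the list, lay 44 of the 431 and 17 of the 108. Without that region, 91 shared WT-MYC peaks and 296 without WBM-MYC had no WDR5 peak. These values argue against loss at WDR5 sites as the whole cause. However, WDR5 below its calling threshold would be missed, and WDR5 was mapped in cells without tagged MYC. As parts of the cause both explanations stay open. Unequal depth or expression of the MYC forms may also act and was not tested, since the lists hold no such values.

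At the end of chromosome 9 (135906641 to 140635243), 2 of 46 WT-MYC peaks overlapped a WDR5 peak (4.35%, 0.531 to 14.8%), against 84.4% elsewhere, and none of the 30 WBM-MYC peaks did. These shares follow from the choice of the region, drawn around gaps between WDR5 peaks, but in fixed 5-Mb bins, 3 of 75 passed the test with a lower share with WDR5 than elsewhere, all on chromosome 9: 47.4% from 130 to 135 Mb, 11.8% from 135 to 140 Mb (3.30 to 27.5%, against 83.9% elsewhere) and 11.8% from 140 to 145 Mb (Fisher's exact test, two-sided, adjusted p = 0.0101, 6.77e-18 and 8.92e-09). Higher DNA copy number in all cells alike would raise WDR5 signal too. The 11.8%, over mostly the same peaks, argues against such a gain as the whole cause. A gain in the transduced cells alone may still act, as WDR5 came from other cells and copy number was measured in neither. As few as the 11 WDR5 peaks from 135 to 140 Mb were held by 124 of 581 other bins. Those bins were taken along all chromosomes, where some low counts were bound to be found, so this number decides nothing. Removal of the region from the WDR5 list by filtering or masking may leave 2 WT-MYC peaks with WDR5 where the share elsewhere gives 38.8, but an absence of WDR5 binding would leave as few, and these cannot be told apart without reads. The 5 Mb just before the region held 75 WDR5 and 23 WT-MYC peaks. The bin from 130 to 135 Mb, at 47.4%, lies before the region and stayed in the analyses made without it. Removal of the region alone would not reach that bin.

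Narrow WT-MYC peaks, those under 496 bp, that overlapped neither partner formed 3 clusters: 2 at chromosome 2 (89185346 to 89247148), 5 at chromosome 14 (106330744 to 107170225) and 4 at chromosome 22 (22453271 to 23223485), with the earliest at lines 4, 5 and 6 of the list. The span on chromosome 22 holds 5 WT-MYC peaks in all and 1 WDR5 peak. Material common to all anti-FLAG precipitates may give such clusters, and WBM-MYC would then have clustered peaks as often as other narrow peaks. With clusters drawn from all narrow peaks whatever their partner, 3 of 15 clustered peaks overlapped WBM-MYC (20%), against 25 of 38 single peaks (65.8%; Fisher's exact test, two-sided, p = 0.00502), which goes against this, but 11 of the 15 are the peaks whose lack of both partners prompted the test, and of the other 4 clustered peaks 3 overlapped WBM-MYC (75%), too few to decide. From general knowledge these places may be those of the immunoglobulin loci, which was not checked, since no hg19 annotation was used here. This material and material in the WT-MYC libraries alone both stay open, and no biological explanation was tested.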

How the results depend on the processing

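Of 62 alternatives, 36 left the result in place (30 of 56 without the 6 void width comparisons), 20 moved a value beyond its 95% interval or spread, 3 lost a call, 3 gained one and none reversed. Overlap beyond random placement held under each alternative run (permutation p = 0.001, the smallest possible). Requiring 50% of the first list's peak gave 67.8% of WBM-MYC peaks on WT-MYC, 74.5% of WT-MYC and 69.1% of WBM-MYC peaks on WDR5, and 10.99% of WDR5 peaks on WT-MYC. Requiring 50% of the shorter peak gave 77.8, 71.2 and 11.9% for the last 3, a WT-MYC to WDR5 distance of 65 bp, and an odds ratio of 0.805 for WDR5 overlap of shared against other WT-MYC peaks. Centres within 500 bp gave 85.1% of WT-MYC on WDR5 and 14.7% of WDR5 on WT-MYC, and merging near peaks gave 14.3% for the latter.

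These alternatives were chosen after the data were seen. With the first 50% of each list, 71.8% of WT-MYC and 64.6% of WBM-MYC peaks lay on WDR5, 10.9% of WDR5 on WT-MYC, and the odds ratio was 0.838; fewer peaks to hit lower such shares by construction. The first 50% of the first list alone gave 32.9% of WT-MYC on WBM-MYC, 81.7% of WBM-MYC on WT-MYC, 71.9% of WBM-MYC on WDR5 and 20.5% of WDR5 on WT-MYC. Without the end of chromosome 9, 84.4% of WT-MYC and 78.9% of WBM-MYC peaks lay on WDR5 and the odds ratio was 0.814; the region holds 17 shared WT-MYC peaks, all without WDR5. WT-MYC peaks with WDR5 came earlier in the file by a median that missed the permutation test (-121.5 lines, p = 0.0663) and passed it with 50% of the shorter peak (-208.5), on autosomes (-136.5) and without the end of chromosome 9 (-168.5); the cause was not tested.

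No paired analysis was possible because the peak lists hold no values per replicate. For the same reason no replicate was left out. Alternatives by score were not possible without one, and those for promoters, gene lists and E-boxes were not run. The planned comparisons of median width are void, since nearly all widths are equal.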

Other observations

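The regions and tests in this part were chosen after the data were seen, and they are given as values.

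Several regions held more MYC peaks than their WDR5 peaks would lead to expect. Of 379 bins of 5 Mb, 8 differed between WT-MYC and WDR5 after adjustment, 7 with more WT-MYC and 1 with less, and 8 held more WBM-MYC (Fisher's exact test, two-sided, Benjamini-Hochberg). Beside the end of chromosome 9, chromosome 16 from 30 to 35 Mb held 24 WT-MYC, 17 WBM-MYC and 52 WDR5 peaks (Fisher's exact test, adjusted p = 0.00153 for WT-MYC and 9.01e-08 for WBM-MYC). Of these, 22 WT-MYC and 16 WBM-MYC peaks lay within 30 to 31 Mb, the densest 1-Mb bin of WT-MYC peaks. Chromosome 1 from 230 to 235 Mb held 23 WT-MYC, 8 WBM-MYC and 44 WDR5 peaks (Fisher's exact test, adjusted p = 0.000637 and 0.0377). Chromosome 6 from 155 to 160 Mb held 17, 10 and 36 (Fisher's exact test, adjusted p = 0.0118 and 0.000759). The bin with less was chromosome 15 from 40 to 45 Mb, with 81 WDR5 peaks and no peak of WT-MYC or WBM-MYC (Fisher's exact test, adjusted p = 0.00237 for WT-MYC and 0.775 for WBM-MYC).

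Long stretches of the genome carried WDR5 peaks and no WT-MYC overlap. The longest run was 142 consecutive WDR5 peaks on chromosome 15, up to 50647139. With WT-MYC overlap permuted among WDR5 peaks of the same file decile, the longest run was 41 to 114 peaks, with a median of 58 (1000 permutations, p = 0.001, the smallest possible). Next came 86 peaks on chromosome 13 (31248765 to 51483965) and 83 on chromosome 16 (31470890 to 58426353). In all, 19 stretches of at least 40 such peaks covered 279 Mb and 1099 WDR5 peaks, 6.40% of the list. WBM-MYC was rare there too: 4 of the 193 WBM-MYC peaks without a WT-MYC peak lay inside (2.07%; odds ratio against WDR5 peaks 0.310, 0.0833 to 0.808, Fisher's exact p = 0.0107). Choosing the stretches by their WDR5 peaks favours a ratio below 1. Among WDR5 peaks without WT-MYC, stratified by decile, the odds ratio of WBM-MYC overlap inside was 0.225 (0.0555 to 0.908, exact conditional p = 0.0175, from 2 peaks inside). WDR5 peaks inside came more often from the last 50% of the file, 64.1 against 49.0% (15.1 points, 12.1 to 18.0), and 64.2 against 53.2% among those without WT-MYC.

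The first 10 lines of the WDR5 list all overlapped a WT-MYC peak and 2 of them a WBM-MYC peak, among them 93297306 to 93298295 on chromosome 1 (line 1, WT-MYC) and 1437986 to 1439201 on chromosome 19 (line 3, both). Of the first 100 lines, 60 overlapped WT-MYC and 9 WBM-MYC. At the top of the WT-MYC list, 73 of the first 100 peaks overlapped WBM-MYC and 65 WDR5.

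Of the 53 narrow WT-MYC peaks, 28 overlapped a WBM-MYC peak and 31 a WDR5 peak. They made up 5.31% of WT-MYC peaks with a WBM-MYC peak (28 of 527) and 1.25% of those without (25 of 2000, Fisher's exact test, two-sided, odds ratio 4.43, p = 2.06e-07). Narrow peaks filled lines 1 to 8 of the file, and in its first decile 60.5% of all WT-MYC peaks overlapped WBM-MYC. File position was not taken into account in this test. Among WT-MYC peaks with WDR5 they made up 1.48% (31 of 2096), against 5.10% of those without (22 of 431, odds ratio 0.279, Fisher's exact p = 1.93e-05). Of these 22 peaks, 11 are the clustered peaks picked out above for lacking both partners, so the odds ratio rests in large part on them. Of the 42 other narrow peaks 31 overlapped a WDR5 peak.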
